A study of Mus musculus with 4 samples.

How the data were processed

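Methylated DNA capture sequencing was performed on satellite cells, the resident stem cells of skeletal muscle, isolated from the hindlimb muscles of 9-week-old mice and grown for 3 days on Matrigel. Mice had received tamoxifen, which activates Cre recombinase and thereby deletes Uhrf1, on 5 consecutive days (150 µl of a 20 mg/ml solution per injection), or oil as control. Sheared genomic DNA was split with an MBD2-based kit into a methylated and a non-methylated part, and libraries of 250 to 350 bp fragments were made from each, per the labels' protocols. The series holds 4 libraries in 4 groups of 1 sample, oil or tamoxifen by methylated or non-methylated DNA. There is no replicate of any group, so no spread between animals or cultures could be estimated and no test across genes was made.

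The data analysed were a single list of regions for the oil and tamoxifen comparison. Per the file headers, the authors called it with MACS 2.2.6, with the oil alignment as the treatment input and the tamoxifen alignment as the control input, so that every listed region is one where the oil library was higher after the tamoxifen tags had been scaled down to its size. In 1 region the unscaled tamoxifen tags were not lower. The list's own name gives the treatments in the opposite order, and the command line was followed. The header names the alignments only as oil and tamoxifen and does not say which DNA part they came from. They are taken here to be the captured, methylated part, and every statement about methylation rests on that reading. Regions higher in tamoxifen were not analysed here, so the balance of gains and losses is not given. Trim Galore, HISAT2 and the mm10 genome are named in the submitters' processing notes.

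Per the file headers, the oil library had 35216008 tags, of which 19534328 were left after at most 1 tag per position and strand was kept (redundant rate 0.45). The tamoxifen library had 36519772 tags, of which 25614791 were left (redundant rate 0.30). Tags of 130 bp were extended to 201 bp, the larger library was scaled to the smaller, no regional background was used and the q cutoff was 1e-04. The deposited pileup, a signal value, is the number of extended oil tags over the region's summit. It is not scaled, because oil was the smaller library. The deposited fold enrichment is the ratio of the oil pileup plus 1 to the scaled tamoxifen value plus 1. The headings of 2 columns had been lost to a spreadsheet error. From their place in MACS output and from the cutoff they were read as the -log10 p and -log10 q values that the authors' caller gave. These p and q values compare 2 libraries and not 2 conditions.

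The tamoxifen tags over each summit were computed from the pileup and the fold. Dividing by the library factor of 0.763 gave a whole number, within 0.02 tags, in 38251 regions (97.5%). In the other 980 regions the value equalled the genome mean of 2.10 scaled tags, the lowest background the caller allows, so that the tamoxifen library had 2 or fewer tags there. The -log10 p values recomputed from these tags differed from the deposited ones by at most 0.00017. Intervals printed beside folds are exact (Clopper-Pearson) 95% limits on the scaled ratio of oil to tamoxifen tags. They cover counting error only, and since the summit is where oil was highest, the folds are biased upward by selection. The ratio of tags has no added 1 and so lies above the fold enrichment of weakly covered regions.

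Regions were placed against the RefSeq gene table of GRCm38.p6, whose primary assembly is that of mm10. The table gives gene ends but neither strand nor exons. The planned promoter, UTR, exon and intron classes therefore could not be formed. A region's midpoint was instead assigned to the first of 3 classes, within 2000 bp of either end of a protein-coding or lncRNA gene, elsewhere inside such a gene, or outside genes. Expected shares came from 1000 random placements of the same regions, each on its own chromosome, within the span from the first to the last annotated gene. A genome sequence was not used here, so CpG content, CpG islands, repeats and assembly gaps were not examined. Because MBD2 capture depends on CpG density, these placements are not matched for capture.

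The 18 gene lists, the comparison, the rule for named genes and the first set of alternatives were chosen before the data were examined. The planned list counts and naming rule used promoters and the 2000 bp upstream of genes. Because the gene table gives no strand, either gene end and 2000 bp on both sides replaced these. For each list, the members with 1 or more regions over the gene and 2000 bp on both sides were counted, out of 34614 genes tested. For single genes and lists, any overlap of 1 bp counted, and a region was near a gene's end when it overlapped the 2000 bp on either side of that end. The midpoint was used only for the 3 classes of place. The count was placed among 10000 random lists of the same size matched on gene length decile. A list was called outside the random range when at most 2.5% of random lists were as high, or as low. With 18 lists, 0.45 would be expected beyond each limit by chance. These percentiles describe the libraries and are not tests of the treatment. The genes named were Uhrf1, Dnmt1, Cdkn1a, Cdkn1b and Notch1, the 10 regions of highest fold in named protein-coding genes, the 10 protein-coding genes with most regions, and up to 4 members per list with the highest fold at a region near a gene end (where there were none, up to 2 members with a region inside the gene). Genes named outside that rule are marked as such.

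Alternatives were stricter q limits, regions above the median fold, merging, other overlaps, protein-coding genes alone for the classes of place, and gene ends alone for the lists. After the data were seen, windows of 1000 and 5000 bp, other library scalings, leaving out regions of very high coverage, a background of protein-coding genes for the lists and joining overlapping list members were added. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. For this comparison, 100% of 5000 simulated tag pairs were recovered, and a simulated excess of regions inside genes of 1.413 was returned as 1.409 over 39231 regions.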

Results

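Captured DNA was sequenced from cultured satellite cells of control (oil) mice and of mice given tamoxifen to delete Uhrf1. The Uhrf1 protein recruits the maintenance DNA methyltransferase Dnmt1 to newly replicated DNA. The oil library held 19534328 tags and the tamoxifen library 25614791 after duplicate removal, with 1 library per treatment and no replicates. All folds below are the authors' oil over tamoxifen values at a region's summit, tags are unscaled counts over that summit, and coordinates are GRCm38 (mm10). With 1 library per treatment, an effect of the deletion cannot be told apart from one of tamoxifen itself, the animals, the culture or the capture. The first question was where captured DNA was lower in the tamoxifen library than in the oil library.

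With the libraries scaled to the same size, the captured signal was lower after tamoxifen in 39231 regions across all 21 chromosomes. The difference was large at most of them. The median region had 51 oil tags over its summit and 14 tamoxifen tags, a median fold of 4.61 (quartiles 3.67 and 5.87). After scaling for library size, the tamoxifen library kept a median of 20.1% of the oil signal (quartiles 15.3% and 25.9%). The fold was 4 or more in 25951 regions (66.1%) and 10 or more in 797 (2.03%), while 260 regions had a fold under 2. Among the latter, 40 regions with 200 or more tamoxifen tags had a median fold of 1.40, which was 1.07 with unscaled tags, and none of them was then past the authors' limit. The regions were short, with a median of 259 bp and a longest of 2313 bp, and together covered 11.5 Mb, or 0.426% of the annotated span. The list compares 2 libraries scaled to the same number of tags, so a change that lowered all tags alike would not show in it. Variation between mice cannot be seen either. Nor can less methylation be told apart from a weaker capture in the tamoxifen library.

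**Figure D1:**
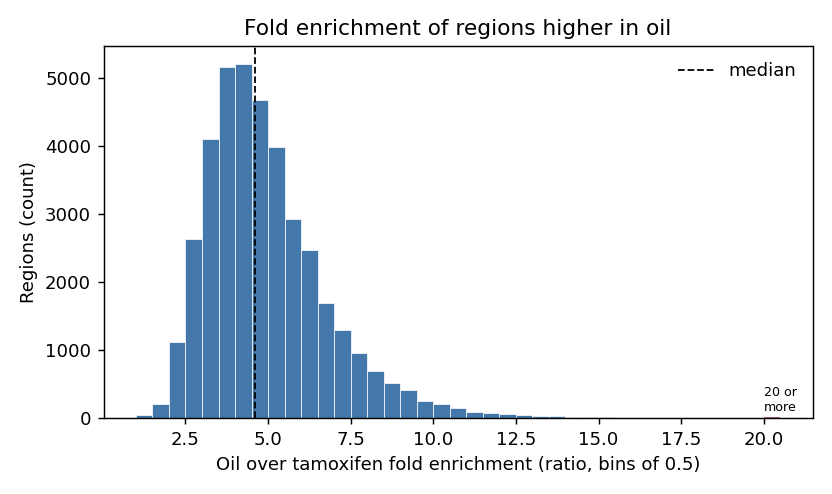
Histogram of the authors' fold enrichment, oil over tamoxifen, in bins of 0.5 for the 39231 regions, with the number of regions on the vertical axis and a last bar for folds of 20 or more. The dashed line marks the median of 4.61, and the lowest fold was 1.31.

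The genes of the methylation machinery themselves held such regions. Uhrf1, on chromosome 17 from 56303337 to 56323486, had 4 regions, all inside the gene and away from its ends. The strongest, from 56309967 to 56310243, fell from 56 oil tags to 6 tamoxifen tags, a fold of 10.22 (95% limits of the tag ratio 5.28 to 34.8), above 98.3% of all regions. The other 3 had folds of 4.91, 7.32 and 4.31. Tags count copies of DNA as well as methylation, and the interval deleted by Cre is not given in the sources used here, so the loss of DNA at Uhrf1 was not separated from a loss of methylation. Dnmt1, the maintenance methyltransferase, had 8 regions over chromosome 9, 20907206 to 20959888, of which 3 (starting at 20907023, 20909491 and 20928630) were not past a q limit of 1e-10. The best covered of all 8, from 20958894 to 20959187 at the gene's right end, had 145 oil and 37 tamoxifen tags (fold 5.00, limits 3.56 to 7.59). The de novo methyltransferase Dnmt3a had a region of 9.67-fold near 1 end (chromosome 12, 3912842 to 3913578, 134 against 17 tags, limits 6.22 to 18.3). Mbd2, which binds methylated DNA, had one of 9.88-fold, and Zbtb4, another reader of methylated CpG, one of 5.98-fold. In all, 13 of 18 genes of this list carried a region, against 9.9 expected from genes of the same length, within the random range of 6 to 14.

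**Figure D2:**
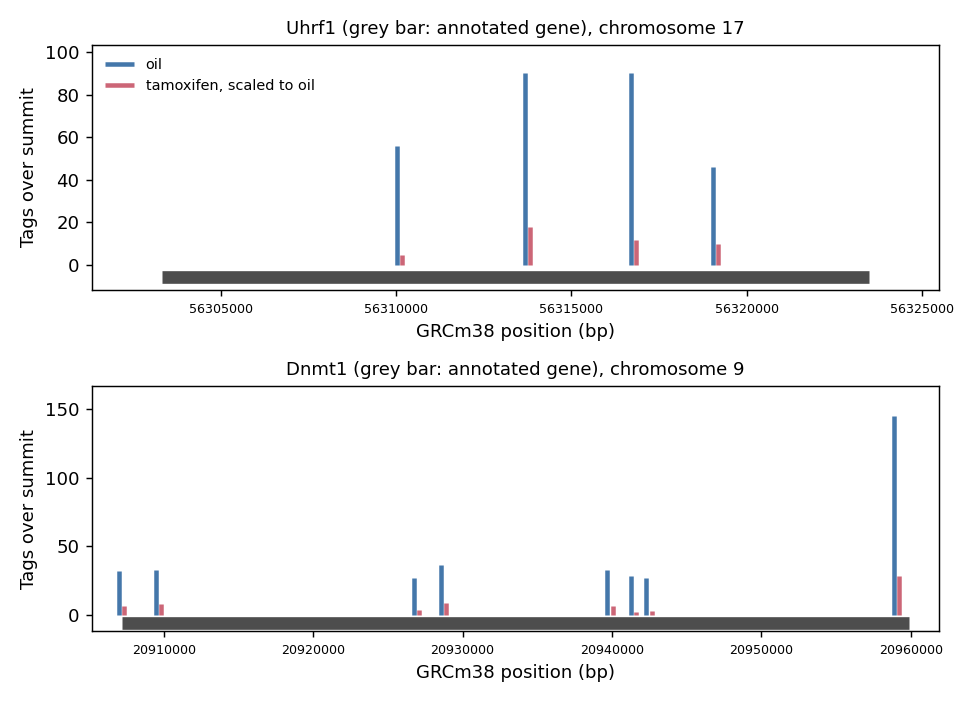
Tags over the summit of each region (vertical axis) by GRCm38 position (horizontal axis) at Uhrf1 and Dnmt1, with 1 bar for the oil library and 1 for the tamoxifen library scaled to oil at each region, and the annotated gene as a grey bar. The 4 regions of Uhrf1 and the 8 of Dnmt1 are higher in oil by construction, as is every listed region.

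The second question was whether regulators of proliferation carried regions. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), and Cdkn1b, which encodes p27 (chromosome 6, 134920401 to 134925525), had none over the gene or 2000 bp on either side. Of 16 inhibitors of the cell cycle, 8 carried a region against 6.4 expected. In this and the other lists, a gene's region counts as near its end when any part of it lies within 2000 bp of that end. For inhibitors these were at the antiproliferative gene Btg1 (6.86-fold, 32 against 5 tags), the CDK4/6 inhibitor gene Cdkn2d (4.55-fold, 73 against 20 tags), Trp53 (3.94-fold, 39 against 12) and the DNA damage response gene Gadd45a (3.60-fold, 41 against 14, not past a q limit of 1e-10). Of 22 drivers of the cycle, 11 carried a region against 8.5 expected. They included the mitotic kinase gene Aurkb (6.91-fold, 27 against 4 tags), E2f2 (5.50-fold, 122 against 28), the topoisomerase gene Top2a (5.07-fold, 151 against 38) and the mitotic cyclin gene Ccnb1 (4.45-fold, 163 against 47). Neither list lay outside the range of random lists, 3 to 10 genes for inhibitors and 4 to 13 for drivers. The list does not tell apart genes that were unmethylated, unchanged, higher in tamoxifen or too thinly covered.

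Genes of the contractile apparatus carried regions more often than random lists of the same gene lengths. Of 26 contractile and fusion genes, 18 carried a region against 10.3 expected, and only 0.11% of random lists were as high. Regions near a gene end were found in 10 of them against 4.7 expected (1.01% of random lists as high). Examples were the embryonic myosin gene Myh3 (11.56-fold, chromosome 11, 67100714 to 67100963, 37 against 3 tags, limits 5.12 to 82.0), the nebulin gene Neb (8.71-fold, 26 tags against 2 or fewer), the actinin gene Actn2 (6.04-fold, 88 against 18) and the desmin gene Des (5.35-fold, 37 against 8). Ttn, which encodes titin, carried 29 regions over 76703980 to 76982557 of chromosome 2. Genes outside the naming rule, picked after their values were seen, were the slow myosin gene Myh7, with 4 regions and a highest fold of 12.84, and the calcium release channel gene Ryr1, with 13 regions and a highest fold of 9.68. At a q limit of 1e-10, 14 contractile and fusion genes kept a region, and the list was inside the random range.

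Of 22 satellite cell and myogenic regulators, 10 carried a region against 10.4 expected, and only Mef2a, a muscle transcription factor gene, did so near a gene end (4.71-fold, chromosome 7, 67232621 to 67232849, 54 against 14 tags). Other members, named outside the rule after their values were seen, went both ways. Megf10 had 6 regions (highest fold 6.86), the growth factor receptor gene Met 4 (5.78), Pax3 2 (4.51) and the calcitonin receptor gene Calcr 1 (4.01), while Pax7, Myf5, Myod1, Myog, Myf6 and Cdh15 had none. The count of 1 gene with regions near an end (3 regions, all of Mef2a), against 4.0 genes expected, is the low end of the random range of 1 to 8, and the difference from the contractile list was not tested. Markers of other cell types that a muscle culture can hold were counted too. Regions lay in 4 of 13 fibro-adipogenic progenitor markers (5.5 expected), 4 of 10 endothelial (5.5), 2 of 10 immune (3.9), 3 of 10 adipogenic (4.7) and 6 of 8 Schwann and neural markers (3.7), all within their random ranges. Examples were Dcn (7.0-fold, 22 against 3 tags), Kdr (4.98-fold, 61 against 15), Ptprc (5.72-fold, 44 against 9), Itgam (4.58-fold, 35 against 9), Ngfr (8.07-fold, 24 against 2 or fewer), Sox10 (5.49-fold, 38 against 8) and Zfp423 (8.39-fold, 33 against 4). The rule also named Gfap (4.99-fold), Prdm16 (4.79-fold), S100b (4.5-fold) and Ebf2 (3.08-fold). The regions of Gfap and Ebf2 were not past a q limit of 1e-10. Such regions give no share of these cells in either culture.

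Notch signalling keeps satellite cells undifferentiated, and 15 of its 26 listed genes carried a region against 11.4 expected, within the random range of 7 to 16. Notch1 had 1 region, inside the gene (chromosome 2, 26465479 to 26465706), with 39 oil and 17 tamoxifen tags and a fold of 2.86 (limits 1.66 to 5.67). That fold exceeded only 8.0% of all regions, and with unscaled tamoxifen tags the region was no longer past the authors' limit (fold 2.22), nor was it past a q limit of 1e-10. Stronger regions near gene ends were at the ligand gene Jag1 (9.04-fold, 77 against 10 tags, limits 5.20 to 21.9), the coactivator genes Maml2 (8.73-fold, 61 against 8) and Maml3 (6.30-fold, 135 against 27, in a gene with 28 regions), and Hes6 (7.16-fold, 28 against 4).

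Gene groups whose silencing depends on DNA methylation were examined next. Of 35 imprinted genes measured, which are expressed from 1 parental allele, 25 carried a region against 16.7 expected (0.11% of random lists as high), and 14 did so near a gene end against 6.0 (0.12%). The region shared by the facing ends of Sgce and Peg10 (chromosome 6, 4746382 to 4746586) had 29 oil and 4 tamoxifen tags, a fold of 7.41 (limits 3.34 to 37.2). Zrsr1 had 1 of 7.91-fold (25 against 3 tags) and Grb10 1 of 7.74-fold (23 tags against 2 or fewer). With overlapping genes joined, 20 of 28 imprinted loci carried a region against 13.6 expected. The count near gene ends was not redone with genes joined, so genes that share a region, such as Sgce and Peg10, count separately in it. Of 30 germline genes that are methylated in somatic cells, 17 carried a region, close to the 15.6 expected, but 11 did so near a gene end against 5.4 expected (1.35% of random lists as high). The latter included the meiotic gene Tex11 on chromosome X (9.16-fold, 99 against 13 tags), Tex101 (7.06-fold, 33 against 5), Dmrtb1 (6.67-fold, 26 against 4) and the piRNA pathway gene Tdrd12 (5.16-fold, 71 against 17). The 13 germline genes without a region included Dazl, Ddx4, Mael, Spo11, Hormad1, Slc25a31 and Sycp2, named outside the rule. Against protein-coding genes alone, the germline count over whole genes fell from the 70.8 to the 48.1 percentile of random lists. Counts near gene ends were not redone against that background for any list. Of 14 pluripotency genes, 7 carried a region against 4.3 expected, within the random range. Among them were Lin28a (8.31-fold), Zfp42 (7.27-fold), Dppa3 (5.09-fold, 105 against 26 tags) and Klf4 (2.98-fold, 27 against 11). With unscaled tamoxifen tags the Klf4 region was 2.33-fold and no longer past the authors' limit. It was also not past a q limit of 1e-06. The 7 genes without a region, named outside the rule, were Pou5f1, Nanog, Sox2, Utf1, Dppa4, Dppa5a and Tdgf1.

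Among the gene families examined, only 44 of 1106 olfactory receptor genes carried a region against 122.5 expected, and none of the 10000 random lists was as low. The strongest of them near a gene end was at Olfr520 (7.60-fold, 24 against 3 tags), followed by Olfr214 (5.98-fold), Olfr221 (5.95-fold) and Olfr156 (5.61-fold). The random lists were not matched on CpG density, on which capture depends, so the low count was not separated from poor capture. Among 369 Zfp zinc finger genes, 170 carried a region against 157.7 expected, within the random range. The highest folds near a gene end were at Zfp85 (10.80-fold, 51 against 5 tags), Zfp536 (10.65-fold, 32 against 2 or fewer) and Zfp513 (9.73-fold). That of Zfp536 was set by the genome mean. Of 57 clustered protocadherins, 39 carried a region against 30.9 expected, and of 39 Hox genes, the developmental patterning genes, 16 did against 9.5. In both families neighbouring genes shared regions. The 39 protocadherins rested on 12 distinct regions, among them 1 of 12.77-fold at the common end of the gamma cluster on chromosome 18 (37841560 to 37841875, 41 against 3 tags), which is counted for Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 and others. With overlapping members joined to loci, 5 of 14 protocadherin loci (4.6 expected) and 7 of 17 Hox loci (5.8 expected) carried a region, both within the random range. Against protein-coding genes alone the Hox list was also inside it. Regions near gene ends were found at Hoxa3 (7.35-fold), Hoxa5 (6.50-fold, 60 against 11 tags) and the end of Hoxc6 that faces Hoxc5 (7.35-fold, 40 against 6).

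**Figure D3:**
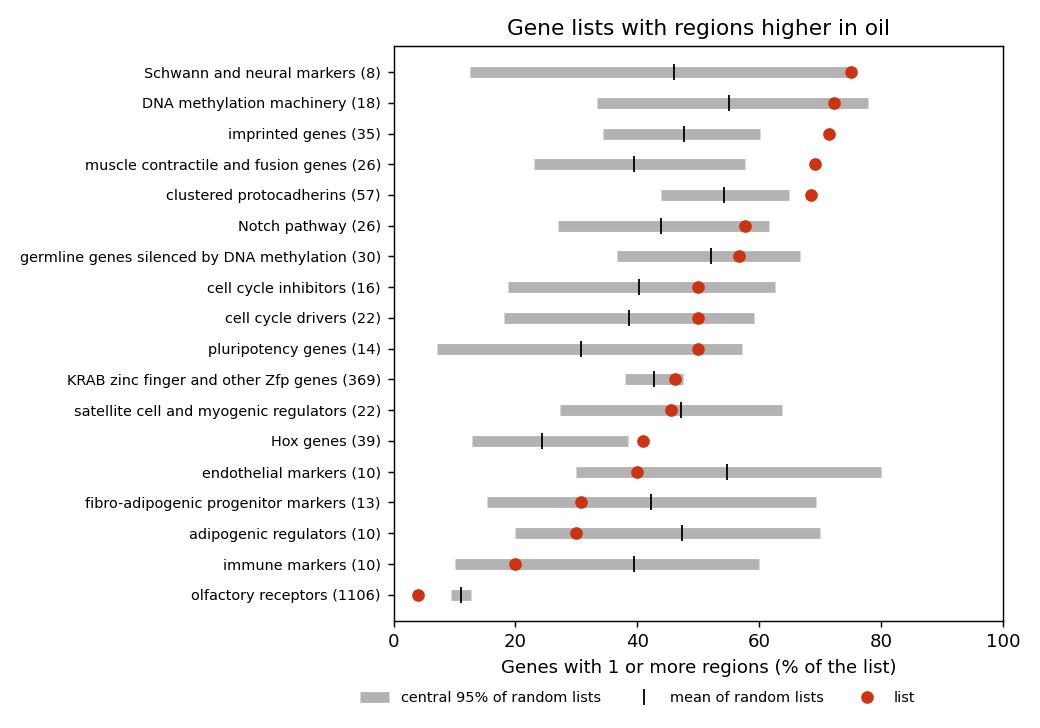
Share of each gene list with 1 or more regions (horizontal axis, in percent; number of genes measured in brackets), with the mean (tick) and central 95% (grey bar) of 10000 random lists matched on gene length. Imprinted genes, contractile and fusion genes, protocadherins and Hox genes lay above the grey bar and olfactory receptors below it. The protocadherin and Hox lists lay inside the random range when overlapping genes were joined.

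The regions of highest fold in protein-coding genes lay mostly inside the gene. So did regions in and near protein-coding and lncRNA genes at large, with 21285 inside and 5813 near an end. A region of the transcription factor gene Zfhx3 (chromosome 8, 108818853 to 108819501) had 130 oil tags and 2 or fewer tamoxifen tags, and its fold of 42.26 was set by the genome mean. Sox12, a SOX-family transcription factor gene, followed with 28.89-fold near a gene end (chromosome 2, 152394943 to 152395292, 94 against 3 tags, limits 13.6 to 203). Flywch1 had a region of 28.14-fold just beyond a gene end (chromosome 17, 23774649 to 23775039, 113 against 4 tags). The next were Dhtkd1 (25.85-fold, 84 against 3), Raly (22.47-fold, 90 against 4), Auts2 (20.67-fold, 130 against 7) and the TGF-beta inhibitor gene Smad7 (20.24-fold, 81 against 4). Then came Rgs9 (20.15-fold, 96 against 5), Adck2 (20.07-fold, 65 against 3) and Sh2d6 (19.68-fold, 60 against 2 or fewer). The fold of Sh2d6 was also set by the genome mean, so its rank is not resolved. The genes with most regions were long. They were Dst (47 regions), Tenm3 (45), Wwox (44), Zfhx3 (43), Cit (40), Fryl (32), Ank3 (31), Camta1 (30), Grip1 (30) and Ttn (29). Among these genes Cit, which encodes the kinase that acts in cytokinesis, had most regions for its length, 24.4 per 100 kb. The values were 13.5 in Fryl, 11.7 in Dst, 10.4 in Ttn and 3.5 in Tenm3. Density per gene length was not compared with that of other genes.

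Across the genome, regions lay in and around genes more often than their random placements. Of the 39231 regions, 5813 (14.8%, exact 95% limits 14.5% to 15.2%) had their midpoint within 2000 bp of a gene end, against 9.14% ± 0.15 (SD over 1000 placements) expected, a ratio of 1.62. Another 21285 (54.3%) lay further inside a gene against 41.7% ± 0.24, a ratio of 1.30, and 12133 (30.9%) lay outside genes against 49.2% ± 0.26, a ratio of 0.63. No placement reached the observed share in either gene class. Both the exact limits and the placements treat regions as independent, though many lay close together, and give no spread between mice. Among the listed regions, the median fold was 4.71 near gene ends, 4.71 inside genes and 4.40 outside. All had passed the same q limit and weaker sites are absent, so depth was not compared over whole classes. In all, 9902 of 21887 protein-coding genes (45.2%) and 3336 of 12727 lncRNA genes (26.2%) carried a region, and 4034 protein-coding genes (18.4%) did so near an end. The placements were not matched on CpG density, and the gene table does not say which end is the promoter.

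The regions were unevenly spread over the chromosomes. Autosomes held 15.8 regions per Mb of annotated span, from 11.81 on chromosome 14 to 21.86 on chromosome 19. Chromosome X held 555 regions, 3.25 per Mb, which is 20.6% of the autosomal density (exact 95% limits 18.9% to 22.4%). These limits also treat regions as independent and cover counting error only. The regions listed on X had a median fold of 4.79 and 48 oil tags, against median folds of 4.50 to 4.71 on the autosomes. All of these had passed the same q limit, so weaker differences are not seen on any chromosome. Chromosome Y held 95 regions, 1.05 per Mb. Of these, 25 lay in the last stretch of the chromosome (90739062 to 90844638) with a median fold of 2.45, and the other 70 had a median fold of 3.99.

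**Figure D4:**
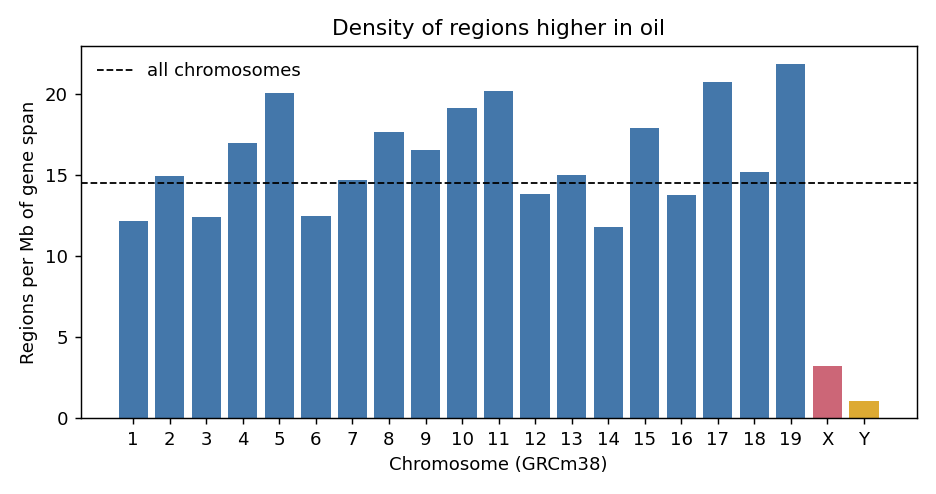
Regions higher in oil per Mb of annotated gene span (vertical axis) on each GRCm38 chromosome (horizontal axis), with the value for all chromosomes together as a dashed line. Chromosome X (3.25 per Mb) and chromosome Y (1.05 per Mb) lie below every autosome (11.81 to 21.86 per Mb).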

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

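The scalings of the tamoxifen tags, the leaving out of very high coverage, the windows of 1000 and 5000 bp, the protein-coding background and the joining of loci were chosen after the data were seen. The number of regions was 37878 at a q limit of 1e-06, 32474 at 1e-10, 37138 with unscaled tamoxifen tags, 37589 with scaling by all tags, 37130 after merging and 39191 under 200 tamoxifen tags; regions at or above the median fold numbered 19628 by construction. The median fold was 4.68 and 4.92 at the stricter q limits, 3.68 unscaled and 3.79 scaled by all tags. Density on chromosome X stayed between 19.6% and 20.6% of the autosomal one. Observed over expected near gene ends, inside and outside genes was 1.68, 1.40 and 0.67 with protein-coding genes only, 1.69, 1.33 and 0.64 with windows of 1000 bp, and 1.58, 1.20 and 0.59 with windows of 5000 bp; the classes themselves differ in these settings. Of 4 lists above the random range, 2 (imprinted, contractile and fusion genes) remained with overlapping members joined, 3 at a q limit of 1e-10 (without contractile and fusion genes) and 3 against protein-coding genes alone (without Hox genes). The olfactory receptor list was below it in all of these settings. With gene ends only, germline genes joined the 4. These counts were redone neither with overlapping members joined nor against protein-coding genes alone. Of 85 distinct named regions, 8 were lost at a q limit of 1e-10 (3 of Dnmt1, and those of Notch1, Gadd45a, Klf4, Gfap and Ebf2), 1 at 1e-06 (Klf4), 2 unscaled (Notch1 and Klf4) and 1 scaled by all tags (Klf4). Alternatives that need sequence, strand or transcripts (CpG-matched placements and lists, CpG islands, repeats, promoter windows) were not run. No paired analysis was possible because each group had 1 library. Depth limits the weakest calls, and tags under the caller's genome mean were not resolved.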

Other observations

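The halving of tags and both tests of the windows of very high coverage were chosen after their results or the values behind them were seen, as were the windows and genes named in the next paragraph, while both tests of gene density were set before those densities were seen.

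Some stretches of 100 kb held many regions lower after tamoxifen. On chromosome 5, the window from 115900001 to 116000000, over the cytokinesis kinase gene Cit, held 25 regions (median fold 3.70), and the window from 115500001 to 115600000, over Pxn, Rplp0 and Gcn1, held 22 (4.02). On chromosome 10, the window from 127500001 to 127600000 held 21 regions (median fold 4.90, 41 oil against 11 tamoxifen tags) over Stac3, a gene of muscle excitation-contraction coupling, Ndufa4l2, Shmt2, Nxph4 and the receptor gene Lrp1. The window of chromosome 10 from 117700001 to 117800000, over the p53 regulator gene Mdm2, Slc35e3 and Nup107, held 19 (5.02). On chromosome 6, 23 regions in the window over Pdia4 (47700001 to 47800000) had a median of 128 oil and 46 tamoxifen tags, above the genome's medians of 51 and 14. They were not confined to that gene. The adjacent window (47600001 to 47700000), over no named protein-coding gene, held 19 regions (median fold 3.06, 90 against 28 tags).

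Chromosome X held 3.25 regions per Mb against 15.8 on the autosomes. If a single X copy had halved the depth there, halving the autosomal tags at random should have removed a similar share, but 81.4% of autosomal regions (SD 0.16 over 20 draws) stayed past the limit, which gives 12.9 per Mb. Gene density accounts for little of the gap, since the fit over 19 autosomes predicted 14.1 per Mb for X, 4.06 residual SDs above the observed value. The sex of the animals is not given in the sources used here, though 70 regions of chromosome Y outside its last stretch had a median of 41 oil and 11.5 tamoxifen tags, so tags mapped to Y in both libraries. The CpG and repeat content and the mappability of X, which may matter for capture, stay open, and no biological explanation was tested.

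The window with most regions was unlike the rest. The window of chromosome 9 from 3000001 to 3100000 held 32 regions with a median of 270 oil and 252 tamoxifen tags and a median fold of 1.43. In the genome, 40 regions had 200 or more tamoxifen tags (median fold 1.40, against 4.62 in the others). Without the scaling of the larger tamoxifen library 100% of the 40 lost their call, and their median fold was 1.07. So did 100% of the 64 other regions with a fold of 1.76 or less lose theirs. These calls thus depended on the scaling, but low folds fix that outcome at any coverage. Whether the scaling had a part particular to very high coverage stays open. The limit of 1 tag per position and strand stays open too, with 7.5% (3 of 40) within 10% of the ceiling it sets in both libraries. One region, on chromosome 2 from 98666435 to 98667126, was at that ceiling in both libraries, and its fold of 1.31 equals the ratio of the library sizes.

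Regions per Mb rose with protein-coding genes per Mb across the 19 autosomes. Spearman's rho was 0.62 (permutation p = 0.0053, Benjamini-Hochberg adjusted 0.01 over 2 coefficients) and Pearson's r 0.57 (permutation p = 0.01, adjusted 0.01), both two-sided with 100000 permutations. Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.73 (permutation p = 0.0011, n = 17). Chromosomes are not replicates of the treatment. CpG density could lie behind both measures and was not examined, so the relation with genes remains a hypothesis.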
